A study of Escherichia coli with 12 samples.

How the data were processed

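RNA from Escherichia coli K-12 cultures was compared on 2-colour arrays, 1 biological replicate per array. Each array carried sample cDNA labelled with Cy5 and reference cDNA labelled with Cy3, and the reference was a pool of RNA from cultures with the control plasmid grown without nitrite. The dyes were never exchanged. Per the labels, 12 arrays fell into 3 groups of 4: pGIT1 (a multicopy plasmid with the ytfE promoter, whose binding site draws the repressor NsrR away from the chromosome) without nitrite, pGIT1 with nitrite (pGIT1_NO2), and pGIT8 with nitrite (pGIT8_NO2). Plasmid pGIT8 is the control and carries the same promoter with 1 base pair missing from the NsrR site. Whether the cloned fragment covers the ytfE probes is not given in the sources used here.

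Some labels conflicted. The characteristics of pGIT1_NO2 replicate 1 name other strains for its channels than its title does; the title was followed, and its ytfE value of 5.88 lay among those of its group. The label of pGIT8_NO2 replicate 4 gives 0.5 mM nitrite where the others give 2.5 mM, the label of pGIT1_NO2 replicate 2 describes no medium, and pGIT1_NO2 replicates 1 and 2 state no pool size where the others give 8 cultures.

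The deposited values are log2 ratios, 1 per spot, in a table of 14400 spots. The log base was read from the values, whose ceiling is log2 of a ratio of 100000 and whose commonest entries are log2 of small whole-number ratios. Scanner settings, background correction and normalization are not given in the sources used here. No sign of centring was seen: the medians of the named probes ran from -0.99 to 0.868 over the 12 arrays. The direction of the ratio is not stated. Sample over reference was taken as likely, since ytfE, a target of NsrR, lay between 2.39 and 5.93 on 11 arrays. That ytfE lay above the reference is therefore no evidence of its own, and only other genes that moved with it or against it add to it. Values at the ceiling (140 to 223 per array) were treated as missing, 432 to 866 spots per array had no value, and 13341 to 13817 were measured. Spot intensities were not used here, so signal over background is unknown, and the number of arrays limits the precision.

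Probes were named from the annotation of the array platform, which pairs 6412 probes with 1 K-12 gene each, 48 with several genes and 7940 with none. The 6412 probes stood for 3204 genes, usually with 2 probes per gene. Symbols were brought up to date by gene identifier with a reference table for assembly ASM584v2, used for names only: 6394 probes matched, and 18 probes of 9 genes kept their older symbols. No probe was named for hcp, nrfB, rnr or norR. The 2 spots of a gene correlated within each array across genes with Spearman's rho of 0.803 to 0.967; genes are not independent replicates.

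One array, pGIT1 replicate 4, was out of register with the rest. Of its 48 blocks of 300 spots, 47 matched the mirror block of the other arrays best and 0 matched their own place, against 21 to 48 in place on each other array. The planned fit of all 12 arrays would have averaged this array gene by gene with spots that it did not match, so it was left out after the data had been seen, and the fit behind every result holds 11 arrays, with 3 in pGIT1. Counts with all 12 arrays as deposited and with its blocks put in order are printed beside each count in the report.

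Each array was centred on the median of its named probes, the probes of a gene were averaged, and a gene needed 3 values in each group. That left 3192 genes, each with a value on all 11 arrays. A linear model with a mean per group was fitted with limma 3.58.1 (R 4.3.3) with its empirical Bayes variance (statmod 1.5.0 for the robust form), and Benjamini-Hochberg adjusted p values under 0.05 were counted as passing. SE in the text is the moderated standard error of limma, SD the spread over the arrays of a group. No array carried the control plasmid without nitrite as a sample. The effect of titration without nitrite and that of nitrite with the control plasmid were therefore tested as log ratios against 0, which leaves out the control's own spread and is open to dye bias. Both also rest on the same kind of reference pool, so part of any overlap between them may come from it. Titration with nitrite (pGIT1_NO2 minus pGIT8_NO2) and nitrite under titration (pGIT1_NO2 minus pGIT1) were contrasts between groups, in which reference and dye cancel. The interaction (pGIT1_NO2 minus pGIT8_NO2 minus pGIT1) keeps 1 log ratio against the reference. Genes called in a pair of comparisons that share no array were counted per direction with a one-sided Fisher's exact test, as a description, since genes of an operon are not independent. The comparisons of a pair also take each gene's spread from the same fit.

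Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 3 measured members, and members were counted by the gene test over all genes and adjusted over the list alone. The lists were NsrR targets known from earlier work, a broader NsrR set, the nrf operon, the nsrR transcription unit, the NorR regulon, the nap-ccm operon, nitrate and cytoplasmic nitrite reductases, anaerobic genes repressed by NarL, TMAO respiration, hydrogenases 1 and 2, the OxyR regulon, SoxRS and Mar, Isc and Suf iron-sulphur cluster assembly, Fur iron uptake, methionine synthesis, arginine synthesis, cysteine and sulphate assimilation, flagella and chemotaxis, acid resistance, RpoS general stress, heat shock, cold shock, the SOS response, copper homeostasis, the lac operon and ribosomal proteins. The broader NsrR set came from the study itself and later work and is not independent evidence here.

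Genes were named by a rule. Per comparison, it took the 10 largest rises and the 10 largest falls among genes that passed with all arrays pointing one way (against 0, on one side of it; between groups, without overlap), and for the interaction the 5 largest each way. It always took ytfE, hmp, ygbA, hcp, hcr, nrfA to nrfG, nsrR and rnr, and per list the 4 members with the smallest p. Groups, comparisons, tests, lists, the rule for named genes and all alternatives except 3 were fixed before the data were examined. The alternatives were values as deposited without centring, quantile normalization, other rules for missing values and probes, array weights, a robust prior, only the groups compared, the replicate number as a block, a log2 change of at least 1, each array left out in turn, camera with an estimated correlation, and fry. Chosen after seeing the data were all 12 arrays as deposited, 12 arrays with the blocks in order, and removal of a trend shared by the arrays.

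The code was tested on simulated data with the group sizes and spread of these arrays, in which 200 of 3192 genes were changed, with independent noise and with a component shared by the genes. With independent noise, 38.8%, 82.1% and 95.5% of genes changed by 0.5, 1 and 2 (log2) were recovered for titration without nitrite, and 56.7%, 89.6% and 98.5% for nitrite with the control plasmid. The same shares were 28.4%, 68.7% and 95.5% for titration with nitrite, 13.4%, 73.1% and 93.9% for nitrite under titration, and 7.46%, 52.2% and 92.4% for the interaction. With the shared component they were 29.9%, 79.1% and 95.5% for titration without nitrite, 34.3%, 79.1% and 97.0% for nitrite with the control plasmid, 23.9%, 77.6% and 97.0% for titration with nitrite, 14.9%, 59.7% and 83.3% for nitrite under titration, and 4.48%, 64.2% and 97.0% for the interaction. Unchanged genes made up 0 to 13 of the 105 to 171 calls per run. With independent noise they passed a share of 0.05 for titration with nitrite (13 of 141), titration without nitrite (11 of 155) and nitrite under titration (8 of 128). They stayed below it for nitrite with the control plasmid (8 of 171) and the interaction (5 of 106). With the shared component they numbered 0 to 3. These are single runs, so they cannot show how often a shared component brings false calls. In a run with independent noise and 1 list shifted, camera called that list and 0 others. This run cannot show how camera at its preset correlation treats lists whose genes vary together. In the data the estimated correlation ran from -0.173 for the nsrR transcription unit to 0.942 for acid resistance.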

Results

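Transcript levels were measured in Escherichia coli K-12 MG1655 cultures grown without oxygen to early exponential phase, with 20 mM trimethylamine N-oxide (TMAO) as electron acceptor. NsrR is a repressor that responds to nitric oxide. It was drawn away from the chromosome by a multicopy plasmid with the ytfE promoter (pGIT1), because deleting nsrR could disturb rnr, a gene of the same transcript. Of the 12 arrays, 4 carried pGIT1 cultures, 4 carried pGIT1 cultures with nitrite and 4 carried control plasmid (pGIT8) cultures with nitrite. Nitrite was at 2.5 mM where a label gives it, except for 0.5 mM in the label of pGIT8_NO2 replicate 4. All arrays were read against pooled RNA of pGIT8 cultures without nitrite. Between 13341 and 13817 of the 14400 spots had a usable log2 ratio per array, and 3192 genes were tested. The number of arrays limits the precision.

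The gene ytfE, a target of NsrR, helps to repair damaged iron-sulphur centres. Whether the cloned fragment covers its probes is not given. If it does, transcript made from a plasmid would enter sample and reference alike, since the reference cultures carried pGIT8 with the same promoter. In which direction this would move the ratio is not known, so the values of ytfE are no clean measure of titration. The direction of all ratios was also taken from ytfE. Its centred log2 ratio was 4.33 to 5.00 on the 3 pGIT1 arrays used, 4.69 to 5.93 with pGIT1 and nitrite, and 2.39 to 3.66 with pGIT8 and nitrite. On pGIT1 replicate 4 as deposited, ytfE lay at 0.23. The spots of that array did not match those of the others in place, so it was not used in the comparisons.

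**Figure D1:**
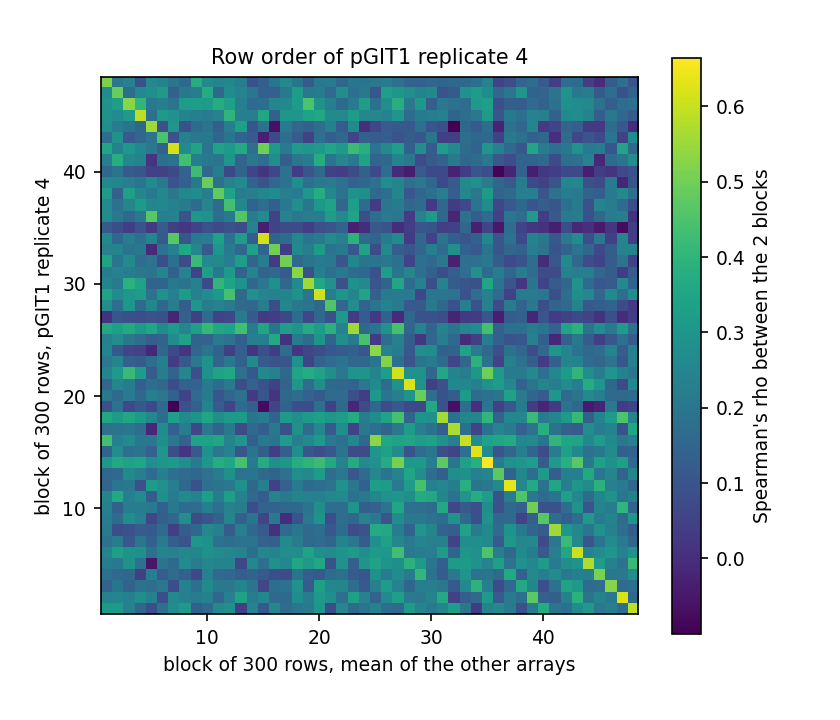
Spearman's rho between each of the 48 blocks of 300 spots on pGIT1 replicate 4 (vertical axis, block number) and each block of the mean of the other arrays (horizontal axis, block number), shown as colour. In 47 of 48 blocks the highest rho lies on the diagonal that pairs a block with its mirror image, and in 0 blocks on the diagonal of equal block numbers.

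Titration without nitrite asks which genes NsrR holds down when no nitrite is added. The ytfE transcript was 26.4-fold higher than in the reference (log2 4.73 ± 0.29 SE, n = 3, adjusted p = 8.8e-06). That of hmp, the nitric oxide-detoxifying flavohaemoglobin, was 11.5-fold higher (3.52 ± 0.30, adjusted p = 0.000102), and that of hcr, the reductase of the hybrid cluster protein, 10.2-fold higher (3.35 ± 0.26, adjusted p = 5.3e-05). The nrf operon for the periplasmic cytochrome c nitrite reductase rose with them. Its first gene nrfA was 4.91-fold higher (SE 0.23, adjusted p = 0.000365), and nrfC rose by 2.06, nrfE by 2.04, nrfD by 1.76 and nrfF by 1.11 on the log2 scale. Rises were also seen for ygbA, of unknown function (2.09 ± 0.24, adjusted p = 0.000838), and yccM, a predicted electron transfer protein (2.22 ± 0.17, adjusted p = 5.3e-05). The leader peptide of the tryptophanase operon, tnaC, was higher by 1.43 ± 0.23 (adjusted p = 0.00751). The last gene of the nrf operon, nrfG, lay at 0.00 ± 0.29 (adjusted p = 0.998), and nsrR itself at 0.04 ± 0.12 (adjusted p = 0.868).

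Lower than in the reference were the genes of the cytochrome bo oxidase, a terminal oxidase of aerobic growth. Of these, cyoA fell by 2.16 (SE 0.26, n = 3, adjusted p = 0.00137), cyoB by 1.90 (adjusted p = 0.00192) and cyoC by 1.58 (adjusted p = 0.00409). The rhamnose mutarotase gene rhaM lay at -2.84 ± 0.30 (adjusted p = 0.000531) and paoC, of the periplasmic aldehyde oxidoreductase, at -2.34 ± 0.44 (adjusted p = 0.0144). Also lower were yagA (-1.90), the porin gene phoE (-1.62), yafE (-1.57), insB4 (-1.49) and ykgF (-1.43). Of 25 alternatives, yagA passed in 13, phoE in 16 and paoC in 20, while insB4 and ykgF passed in all. The call of paoC was lost without any 1 of the 3 pGIT1 arrays, without centring and with all 12 arrays as deposited. In all, 159 genes passed, 90 higher and 69 lower, of which 29 changed at least 2-fold. All 3 arrays lay on one side of 0 for each of the 159. With all 12 arrays as deposited the count was 67 (35 higher, 32 lower), and with the blocks of pGIT1 replicate 4 in order it was 495 (309 and 186).

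Among the fixed lists, all 3 NsrR targets known from earlier work were higher, and 3 adjusted over the list alone. Their mean was 3.44 (camera adjusted p = 8.7e-08, adjusted p = 0.0706 with an estimated correlation). The list holds ytfE, from which the direction of the ratio was taken. In the broader NsrR set, which the study itself helped to define and which is not independent evidence, 7 of 11 measured genes were higher, and 9 adjusted over the list alone. Its mean was 1.26 (adjusted p = 1.1e-10, adjusted p = 0.0706 with an estimated correlation). The nrf operon had 5 of 6 genes higher by either count (mean 1.54, adjusted p = 1.5e-08, adjusted p = 0.12 with an estimated correlation). Cysteine and sulphate assimilation had 4 of 13 genes higher, and 8 adjusted over the list alone (mean 0.57, adjusted p = 2.0e-06, adjusted p = 0.425 with an estimated correlation). They were cysD and cysN for sulphate adenylyltransferase (1.15 and 0.79), and cysP and cysA of the sulphate importer (0.94 and 0.80).

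Anaerobic genes repressed by NarL had 3 of 11 genes higher, and 5 adjusted over the list alone. These were the dicarboxylate carrier gene dcuB at 0.94, the fumarase gene fumB at 0.81 and frdA of fumarate reductase at 0.60. The mean was 0.47 (adjusted p = 2.1e-05, adjusted p = 0.43 with an estimated correlation). Hydrogenases 1 and 2 had hybA and hybB higher (0.53 and 0.63), and 3 genes adjusted over the list alone. Their mean of 0.22 (14 genes, adjusted p = 0.0129, adjusted p = 0.612 with an estimated correlation) became -0.20 without centring.

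Cold shock genes were lower as a list (7 genes, mean -0.46, adjusted p = 0.00228, adjusted p = 0.0706 with an estimated correlation). Of them cspB at -0.68 and cspG at -0.61 passed, and 4 adjusted over the list alone. SOS response genes were lower too (10 genes, mean -0.35, adjusted p = 0.000477, adjusted p = 0.504 with an estimated correlation), with umuC of the error-prone polymerase at -0.53, and 5 adjusted over the list alone. Fur iron uptake genes had a mean of -0.18 (26 genes, adjusted p = 0.0396, adjusted p = 0.635 with an estimated correlation), and 0 passed by limma over all genes or adjusted over the list alone. With 1 array left out the mean of Fur iron uptake ran from -0.26 to -0.11 and that of hydrogenases 1 and 2 from 0.13 to 0.30, and each lost its call without 1 array. The adjusted p was under 0.05 in 15 of 25 alternatives for cspG and in 16 for cspB and hybA. These numbers do not apply the log2 change of at least 1, which the 3 genes did not reach. Leaving out pGIT1 replicate 1, 2 or 3 left 35, 58 or 18 genes, pGIT1_NO2 replicate 1 or 3 left 91 or 105, and pGIT8_NO2 replicate 2 left 86. Without centring the median gene moved by -0.42 and 23 genes passed (9 higher, 14 lower), so changes are relative to the median gene. With quantile normalization 388 passed (208 and 180).

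**Figure D2:**
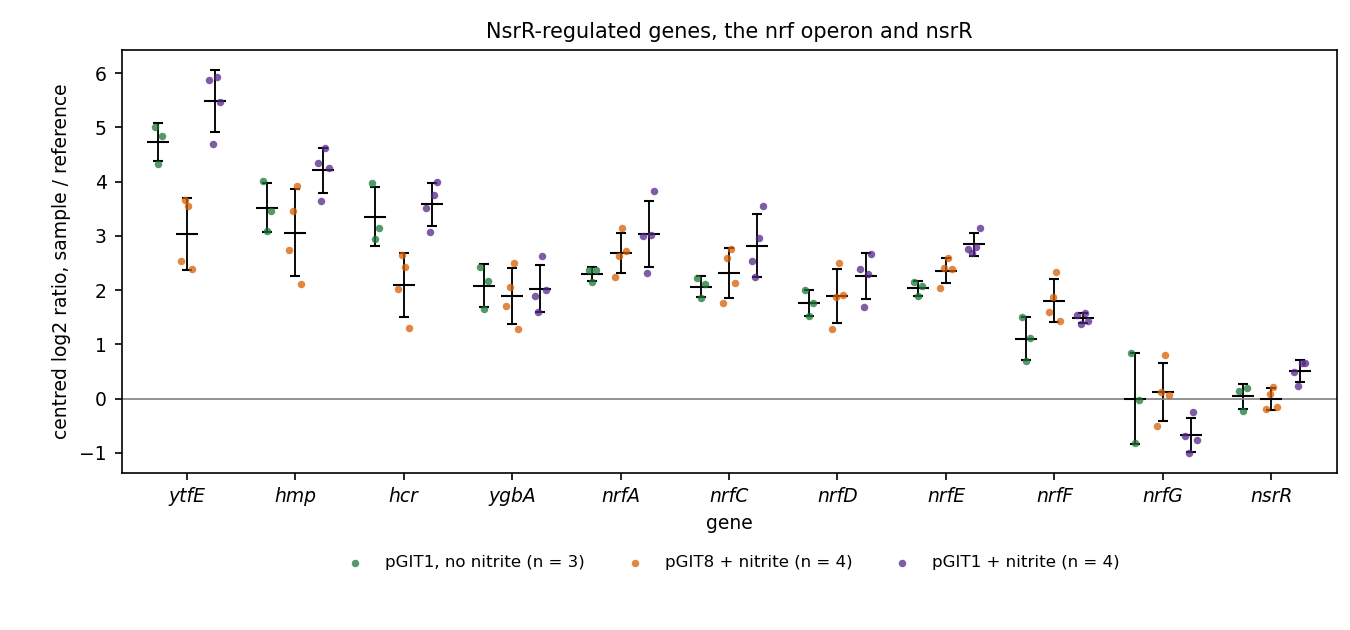
Centred log2 ratio of sample over reference (vertical axis) for NsrR-linked genes on each array, by group (pGIT1, 3 arrays, pGIT1_NO2, 4, and pGIT8_NO2, 4), with points for arrays, bars for group means and error bars for SD. The mean of ytfE was 4.73 with pGIT1, 5.49 with pGIT1 and nitrite, and 3.04 with pGIT8 and nitrite, while nsrR lay at 0.04 with pGIT1.

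Nitrite with the control plasmid shows the response of cells whose NsrR was not titrated. Targets of NsrR rose, hmp by 8.34-fold (log2 3.06 ± 0.26 SE, n = 4, adjusted p = 5.9e-05), ytfE by 3.04 ± 0.25 (adjusted p = 5.3e-05), nrfA by 6.42-fold (2.68 ± 0.20, adjusted p = 3.3e-05) and nrfE by 5.13-fold (2.36 ± 0.11, adjusted p = 7.0e-07). So did nrfC (2.31), hcr (2.10), nrfD (1.89), ygbA (1.89) and nrfF (1.81). Neither nrfG at 0.12 (adjusted p = 0.731) nor nsrR at -0.01 (adjusted p = 0.943) passed. Genes of nitrate and nitrite metabolism were also higher. The periplasmic nitrate reductase gene napF rose by 3.71-fold (SE 0.25, adjusted p = 0.00106), nirB of the cytoplasmic nitrite reductase by 3.29-fold (1.72 ± 0.12, adjusted p = 3.3e-05) and the transporter gene narK by 2.80-fold (1.49 ± 0.26, adjusted p = 0.00439). The ratio of yeaR, of unknown function, was higher by 2.0 ± 0.17 (adjusted p = 5.7e-05).

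Lower were paoC (-2.41 ± 0.38, adjusted p = 0.00253), the copper efflux genes cusC (-2.15 ± 0.29, adjusted p = 0.00121) and cusF (-1.92), and rhaM (-2.09). The anaerobic fumarase gene fumB was 3.98-fold lower (-1.99 ± 0.16, adjusted p = 4.2e-05), and dcuB 3.84-fold lower (-1.94 ± 0.14, adjusted p = 3.3e-05). Falls were also measured for yafE, the flagellin chaperone gene fliS (-1.47), the serine receptor gene tsr (-1.43) and hycA, a regulator of formate hydrogenlyase (-1.34). Over all genes 414 passed, 164 higher and 250 lower, 50 of them at least 2-fold. For 395 of them all 4 arrays lay on one side of 0. The count was 312 (120 and 192) with all 12 arrays as deposited and 487 (192 and 295) with the blocks in order.

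In flagella and chemotaxis 27 of 30 genes were lower, and 30 adjusted over the list alone (mean -0.84, adjusted p = 2.7e-20, adjusted p = 0.191 with an estimated correlation). Besides fliS these included fliD for the filament cap (-1.25), the chemotaxis gene cheW (-1.20) and flgH of the basal body (-0.96). The nap-ccm operon, which encodes the periplasmic nitrate reductase and cytochrome c maturation, had 11 of 13 genes higher, and 13 adjusted over the list alone. Its mean was 1.13 (adjusted p = 6.3e-11, adjusted p = 0.18 with an estimated correlation), with napD at 1.76, napH at 1.75 and napG at 1.67. Of 11 nitrate and cytoplasmic nitrite reductase genes, nirB, narK and nirD (1.48) were higher, and 4 adjusted over the list alone (mean 0.66, adjusted p = 0.000164, adjusted p = 0.349 with an estimated correlation).

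All 3 NsrR targets known from earlier work rose by either count (mean 2.66, adjusted p = 1.6e-05, adjusted p = 0.18 with an estimated correlation). So did 9 of 11 genes of the broader NsrR set by either count, which is not independent evidence (mean 1.56, adjusted p = 5.2e-11, adjusted p = 0.18 with an estimated correlation), and 5 of 6 genes of the nrf operon by either count (mean 1.86, adjusted p = 3.3e-08, adjusted p = 0.18 with an estimated correlation). In TMAO respiration, torC and torD of the TMAO reductase operon were higher (0.66 and 0.60), and 4 of 6 adjusted over the list alone (mean 0.39, adjusted p = 0.0260, adjusted p = 0.18 with an estimated correlation).

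Hydrogenases 1 and 2 had 10 of 14 genes lower, with hyaD at -0.73 and hyaA at -0.69, and 11 adjusted over the list alone (mean -0.45, adjusted p = 1.4e-07, adjusted p = 0.18 with an estimated correlation). Anaerobic genes repressed by NarL had 4 of 11 lower, including dcuB, fumB and the alcohol dehydrogenase gene adhE at -0.79, and 6 adjusted over the list alone (mean -0.65, adjusted p = 1.6e-05, adjusted p = 0.337 with an estimated correlation). Copper homeostasis had 5 of 9 lower by either count (mean -0.70, adjusted p = 0.00160, adjusted p = 0.18 with an estimated correlation). Heat shock genes had a mean of -0.28 (13 genes, adjusted p = 0.0161, adjusted p = 0.965 with an estimated correlation), with 0 passing by limma over all genes or adjusted over the list alone. Their mean was -0.58, -0.20, 0.38 and -0.69 on pGIT8_NO2 replicates 1 to 4. It ran from -0.49 without replicate 3 to -0.14 without replicate 4, and the call was lost without replicate 1 or 4. That of TMAO respiration was lost without 1 array. Without pGIT8_NO2 replicate 3, 1374 genes passed, and without replicate 1, 2 or 4 of that group 196, 191 or 212. Without centring 31 passed (20 higher, 11 lower), with quantile normalization 336 (73 and 263), and with only the groups compared 74 (31 and 43), which ended the calls of hycA, narK, adhE, torC, torD, hyaD and hyaA.

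**Figure D3:**
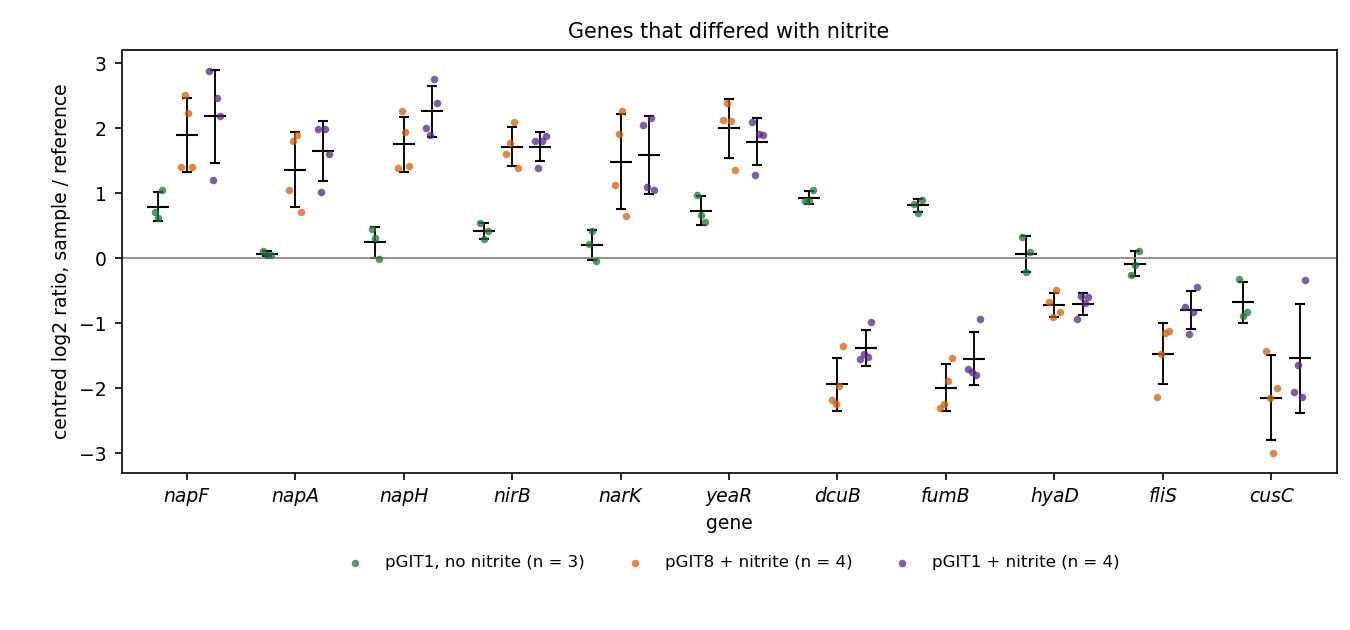
Centred log2 ratio of sample over reference (vertical axis) for genes of nitrate and nitrite metabolism, anaerobic metabolism, motility and copper efflux on each array, by group (pGIT1, 3 arrays, pGIT1_NO2, 4, and pGIT8_NO2, 4), with points for arrays, bars for group means and error bars for SD. With pGIT8 and nitrite the mean of napF was 1.89 and that of dcuB -1.94.

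Titration with nitrite asks whether drawing NsrR away still changes transcripts once nitrite is there. The ytfE transcript was 5.48-fold higher with pGIT1 than with pGIT8 (log2 2.45 ± 0.35 SE, n = 4 and 4, adjusted p = 0.0286). The toxin genes mqsR (1.49 ± 0.21, adjusted p = 0.0286) and higB (0.77 ± 0.11, adjusted p = 0.0286) and the cold shock gene cspA (1.37 ± 0.23, adjusted p = 0.0447) were higher as well. Smaller rises were those of fimB, a recombinase gene for type 1 fimbriae (0.92), recX, an inhibitor of RecA (0.81), umuD (0.73), dedA (0.67), pptA (0.65) and acpT (0.65). The sodium-proton antiporter gene nhaA (-0.78 ± 0.13, adjusted p = 0.0447) and ycgX (-0.76 ± 0.12, adjusted p = 0.0370) were lower. Other NsrR-linked genes did not pass, with hcr at 1.48 ± 0.32 (adjusted p = 0.081), hmp at 1.15 ± 0.37 (adjusted p = 0.11) and nrfA at 0.35 ± 0.28 (adjusted p = 0.355). With quantile normalization ytfE lay at 0.77, short of the threshold, hmp at -0.08 and nrfA at -0.70. Quantile normalization gives all arrays the same set of values, so by its design it can shrink differences in genes that rank near the top in both groups. These values are therefore no clean measure of the difference. The value of ygbA was 0.13 ± 0.29 (adjusted p = 0.736) and that of nsrR 0.52 ± 0.15 (adjusted p = 0.104). The array labelled with 0.5 mM nitrite, pGIT8_NO2 replicate 4, was the lowest of its group for ytfE (2.39), hmp and hcr. For nrfA (2.72) it was not the lowest. Without that array the difference in ytfE was 2.24. Whether a lower dose of nitrite added to the differences in this comparison was not tested.

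In all, 13 genes passed, 11 higher and 2 lower, 3 of them at least 2-fold, and for each of the 13 the arrays of both groups did not overlap. At an unadjusted p under 0.05 there were 937. The count was 2 with all 12 arrays as deposited and 28 (23 and 5) with the blocks in order. Without centring 1 gene was higher and 0 lower, and with quantile normalization 5 were higher and 0 lower. With only the groups compared the count was 0 by limma (747 at an unadjusted p under 0.05). The NsrR targets known from earlier work had a mean of 1.25 and were not called (adjusted p = 0.0713), with 2 of 3 higher adjusted over the list alone. Nor was the broader NsrR set, not independent evidence, at a mean of 0.13 (adjusted p = 0.703). Without pGIT8_NO2 replicate 3, 1388 genes passed, without pGIT1_NO2 replicate 2, 63, without pGIT1 replicate 1, 4, and without any other array 0 by limma (492 to 883 at an unadjusted p under 0.05). Over these omissions ytfE stayed between 2.24 and 2.72, with adjusted p from 0.0150 to 0.146. Over all 25 alternatives it passed in 13, with a lowest value of 0.77 and a highest adjusted p of 0.164. It was lost with quantile normalization, with the replicate number as a block, with only the groups compared, with all 12 arrays as deposited and without any 1 of 8 arrays. The other genes named above as passing had an adjusted p under 0.05 in 9 (dedA and pptA) to 14 (mqsR) of the 25. These numbers take the alternative of a log2 change of at least 1 by its adjusted p alone, and of these genes only mqsR and cspA reached that change.

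SOS response genes were called higher (10 genes, mean 0.48, adjusted p = 0.000811, adjusted p = 0.864 with an estimated correlation), with umuD passing, and 5 adjusted over the list alone. Anaerobic genes repressed by NarL had a mean of 0.39 (11 genes, adjusted p = 0.013, adjusted p = 0.864 with an estimated correlation), with 0 passing by limma over all genes and 1 adjusted over the list alone. For ribosomal proteins the mean was 0.48 (54 genes, adjusted p = 5.9e-09, adjusted p = 0.864 with an estimated correlation), and for flagella and chemotaxis 0.43 (30 genes, adjusted p = 1.9e-05, adjusted p = 0.864 with an estimated correlation). In both, 0 genes passed by limma over all genes or adjusted over the list alone. For all 4 lists the means per array overlapped between the groups. That of the ribosomal proteins was 0.51 on pGIT8_NO2 replicate 3 against -0.41 to -0.09 on the rest of its group, and 0.00 on pGIT1_NO2 replicate 2 against 0.38 to 0.67 on the rest of its group. For the SOS response the same arrays stood apart, at 0.32 against -0.32 to -0.03, and at 0.17 against 0.48 to 0.59.

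Nitrite under titration compares pGIT1 cultures with and without nitrite, where NsrR was drawn away in both. Genes of the periplasmic nitrate reductase rose, napC by 4.10-fold (log2 2.04 ± 0.35 SE, n = 4 and 3, adjusted p = 0.0155), napH by 4.06-fold (2.02 ± 0.26, adjusted p = 0.00492), napG by 1.81 and napA by 1.58 on the log2 scale. The nitrite reductase gene nirB was 2.46-fold higher (adjusted p = 0.00601). The cold shock genes cspA (1.62 ± 0.25, adjusted p = 0.0107) and cspG (1.42 ± 0.20, adjusted p = 0.00601) were higher. Other single genes that rose were recX, by 2.65-fold (SE 0.15, adjusted p = 0.00137), the DNA recombination gene rmuC, by 1.33 ± 0.13 (adjusted p = 0.000814), the SOS repressor gene lexA by 1.26 ± 0.20 (adjusted p = 0.0118), dinI by 1.19 and umuD by 1.02. Most targets that titration had raised did not pass here. The value of ytfE was 0.77 ± 0.38 (adjusted p = 0.4), that of hmp 0.69 (adjusted p = 0.485), that of hcr 0.23 (adjusted p = 0.89), that of ygbA -0.06 (adjusted p = 0.983) and that of nrfA 0.74 (adjusted p = 0.282). Of the nrf operon nrfE passed, at 0.81 ± 0.16 (adjusted p = 0.0308), but its adjusted p was under 0.05 in only 13 of 25 alternatives, with values down to 0.19. It was lost without centring, with quantile normalization, with every probe on its own, with the replicate number as a block, with all 12 arrays as deposited and without any 1 of 7 arrays. Among the rises named above, napA passed in 18 of 25 alternatives, dinI in 19, napC in 21 and the others in 22 to 24.

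Lower with nitrite were fumB, by 5.13-fold (-2.36 ± 0.24, adjusted p = 0.00109), dcuB, by 4.98-fold (-2.32 ± 0.22, adjusted p = 0.000814), and the citrate lyase gene citD (-1.94 ± 0.42, adjusted p = 0.0381). Relatives of the dimethyl sulphoxide reductase genes were lower too, ynfG by 2.46-fold, ynfH by 2.40-fold and ynfE by 2.15-fold. The ribosome modulation factor gene rmf (-1.34), the lysyl-tRNA synthetase gene lysU (-1.31), bssR (-1.30) and cspD (-1.01) were also lower. These calls were less stable, with an adjusted p under 0.05 in 11 of 25 alternatives for lysU, 12 for cspD (with values up to -0.46), 15 for rmf and for citD, and 18 for bssR. Over all genes 83 passed, 53 higher and 30 lower, 29 of them at least 2-fold. For all 83 the arrays of both groups did not overlap. The count was 73 (51 and 22) with all 12 arrays as deposited and 151 (89 and 62) with the blocks in order.

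The nap-ccm operon had 6 of 13 genes higher, ccmC by 2.15-fold among them, and 10 adjusted over the list alone (mean 1.2, adjusted p = 4.35e-13, adjusted p = 0.224 with an estimated correlation). The SOS response had 3 of 10 higher and 10 adjusted over the list alone (mean 0.79, adjusted p = 7.6e-11, adjusted p = 0.224 with an estimated correlation). Its central recombinase gene recA lay at 1.12 (adjusted p = 0.0565). Cold shock had cspA and cspG of 7 genes higher, and 3 adjusted over the list alone (mean 0.85, adjusted p = 2.5e-06, adjusted p = 0.0236 with an estimated correlation). This was the only list call of all 4 comparisons tested that held with an estimated correlation. The estimate for cold shock was -0.040, so this setting did not raise its correlation as it did for most other called lists. Nitrite with the control plasmid changed neither list, with means of -0.02 for cold shock and -0.04 for the SOS response (camera adjusted p = 0.841 for each). The pGIT1 arrays, low against the reference for both lists (means -0.46 and -0.35), enter this comparison as well as titration without nitrite. The 2 sets of calls are therefore not independent. The nitrate and cytoplasmic nitrite reductases had nirB of 11 genes higher, and 2 adjusted over the list alone (mean 0.67, adjusted p = 7.8e-06, adjusted p = 0.337 with an estimated correlation). Ribosomal proteins had a mean of 0.38 (54 genes, adjusted p = 6.5e-09, adjusted p = 0.492 with an estimated correlation), with 0 passing by limma over all genes or adjusted over the list alone. On pGIT1_NO2 replicate 2 their mean was 0.00, among the -0.12 to 0.19 of the pGIT1 arrays.

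In the broader NsrR set, not independent evidence, 1 of 11 was higher and 3 adjusted over the list alone (mean 0.43, adjusted p = 0.0147, adjusted p = 0.439 with an estimated correlation). The nrf operon had 1 of 6 higher by either count (mean 0.42, adjusted p = 0.0159, adjusted p = 0.455 with an estimated correlation). Isc and Suf iron-sulphur cluster assembly had its regulator gene iscR higher at 0.70, 1 of 11 by either count (mean 0.25, adjusted p = 0.0302, adjusted p = 0.583 with an estimated correlation). The adjusted p of iscR was under 0.05 in 13 of 25 alternatives. Acid resistance genes had a mean of 0.49 (8 genes, adjusted p = 0.00725, adjusted p = 0.492 with an estimated correlation), with 0 passing by limma over all genes or adjusted over the list alone. On pGIT1 replicate 1 their mean was 0.27, against -0.57 and -0.56 on the other pGIT1 arrays, and without that array the difference was 0.77. With 1 array left out the difference of the nrf operon ran from 0.25 to 0.57 and that of Isc and Suf from 0.17 to 0.41.

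Lower as a list were the anaerobic genes repressed by NarL, with fumB and dcuB of 11 genes passing, and 3 adjusted over the list alone (mean -0.73, adjusted p = 1.5e-06, adjusted p = 0.337 with an estimated correlation). Hydrogenases 1 and 2 had hyaD at -0.77 (adjusted p under 0.05 in 12 of 25 alternatives) and 6 of 14 lower adjusted over the list alone. Their mean was -0.41, or 0.14 without centring (adjusted p = 5.2e-07, adjusted p = 0.337 with an estimated correlation). In cysteine and sulphate assimilation 0 of 13 genes passed by limma over all genes, while adjusted over the list alone 10 were lower and 1 higher (mean -0.58, adjusted p = 1.5e-06, adjusted p = 0.337 with an estimated correlation). Flagella and chemotaxis had a mean of -0.49, or 0.06 without centring (30 genes, adjusted p = 1.2e-10, adjusted p = 0.41 with an estimated correlation). Copper homeostasis had a mean of -0.32, or 0.24 without centring (9 genes, adjusted p = 0.0417, adjusted p = 0.41 with an estimated correlation). In these last lists 0 genes passed by limma over all genes or adjusted over the list alone. The means per array overlapped between the groups for 8 of the 14 lists, namely the broader NsrR set, the nrf operon, Isc and Suf, cysteine and sulphate assimilation, flagella and chemotaxis, acid resistance, copper homeostasis and ribosomal proteins. The call was lost without any 1 of 4 arrays for Isc and Suf and for copper homeostasis, of 2 for acid resistance and the broader NsrR set, and of 1 for the nrf operon. Without centring the median gene moved to 0.55 and 1 gene passed, which was higher. Counts fell to 12 without pGIT1 replicate 3, 22 without pGIT1_NO2 replicate 1 or 3, 23 without pGIT1 replicate 1 or 2, and 41 without pGIT8_NO2 replicate 2.

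**Figure D4:**
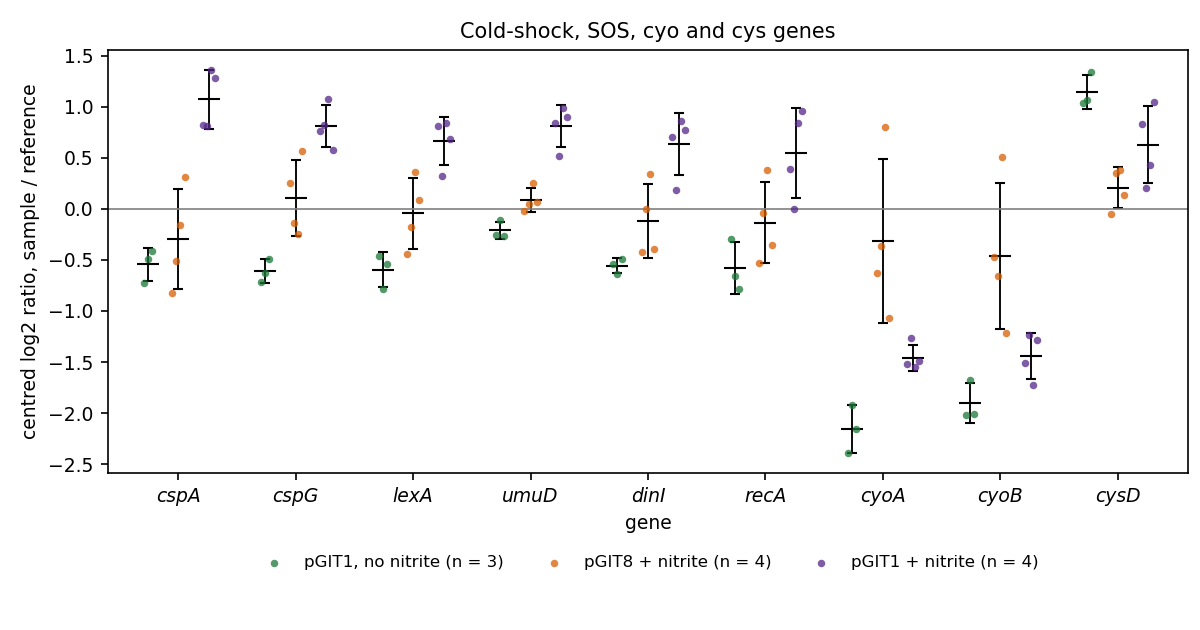
Centred log2 ratio of sample over reference (vertical axis) for cold shock, SOS response, cytochrome bo oxidase and sulphate assimilation genes on each array, by group (pGIT1, 3 arrays, pGIT1_NO2, 4, and pGIT8_NO2, 4), with points for arrays, bars for group means and error bars for SD. The cold shock gene cspA was higher with pGIT1 and nitrite than with pGIT1 by 1.62 and than with pGIT8 and nitrite by 1.37.

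Whether titration and nitrite added up was tested by their interaction, the change with both minus the sum of the separate changes. It was negative for several genes that each treatment raised, with ygbA at -1.95 ± 0.38 (SE, adjusted p = 0.043), nrfA at -1.94 ± 0.36 (adjusted p = 0.043), yccM at -1.90 ± 0.28 (adjusted p = 0.0219), nrfE at -1.55 ± 0.19 (adjusted p = 0.0115) and nrfF at -1.43 ± 0.28 (adjusted p = 0.043). The values of hmp (-2.37 ± 0.48, adjusted p = 0.0518), ytfE (-2.27 ± 0.46, adjusted p = 0.0507) and hcr (-1.87 ± 0.42, adjusted p = 0.076) did not pass. It was positive for cspA (1.91 ± 0.30, adjusted p = 0.0359), paoC (4.11 ± 0.70, adjusted p = 0.043), rhaM (2.42), yafE (1.58) and ykgF (1.53). The means of paoC, rhaM, yafE and ykgF lay below 0 in all 3 groups. The interaction keeps 1 log ratio against the reference, so a bias of dye or reference alone would make it positive for these 4 genes and negative for genes high in all 3 groups, as ygbA, nrfA, yccM, nrfE and nrfF were. The genes named as passing had an adjusted p under 0.05 in 11 (rhaM and nrfF) to 19 (ykgF) of 24 alternatives. None of them did with the replicate number as a block. In all, 27 genes passed, 20 higher and 7 lower, 15 of them at least 2-fold, and 417 had an unadjusted p under 0.05. By limma the count was 0 with all 12 arrays as deposited (349 at an unadjusted p under 0.05) and 53 (38 and 15) with the blocks in order.

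The interaction count was 88 without pGIT8_NO2 replicate 3, 7 without pGIT8_NO2 replicate 1, 5 without pGIT1_NO2 replicate 4, 3 without pGIT1_NO2 replicate 1, 2 without pGIT1 replicate 1 or 2, 1 without pGIT1_NO2 replicate 3, and 0 by limma without pGIT1 replicate 3 or pGIT8_NO2 replicate 2 (336 at an unadjusted p under 0.05 in either case). Without centring it was 0 by limma as well (260 at an unadjusted p under 0.05), and the median gene moved to 0.46. With the replicate number as a block it was also 0 by limma (435 at an unadjusted p under 0.05).

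Overlap was counted between comparisons that share no array. Both comparisons of a pair take each gene's spread from the same fit, so a gene with a small spread passes more readily in both. The numbers expected of independent lists do not allow for this. Nitrite raised 22 genes with pGIT8 and again with pGIT1 (2.72 expected of independent lists, one-sided Fisher's exact p = 1.3e-15). Among them were napA, napC, napG, napH, nirB, ccmC, ccmE, nrfE, rmuC and the DNA damage-inducible genes dinB, dinF and sbmC. It lowered 14 in both (2.35 expected, one-sided Fisher's exact p = 1.1e-08), among them dcuB, fumB, hyaD, ynfE, ynfG, ynfH, hycG and the oxidase genes appB and appC. Titration raised 1 gene, ytfE, without and with nitrite (0.310 expected, one-sided Fisher's exact p = 0.27) and lowered 1, ycgX (0.0432 expected, one-sided Fisher's exact p = 0.0428). The nitrite overlap of 36 was 35 with all 12 arrays as deposited and 69 with the blocks in order, and the titration overlap of 2 was 0 and 12. Without pGIT1 replicate 1, 2 or 3 the nitrite overlap was 12, 14 or 8, without pGIT1_NO2 replicate 1 or 3 it was 11 or 13, and without pGIT8_NO2 replicate 2 it was 17. The titration overlap was 82 without pGIT8_NO2 replicate 3, 15 without pGIT1_NO2 replicate 2, 1 without pGIT1 replicate 1, and 0 without any other array.

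Several lists were called by camera in no comparison, and their means are given with camera's adjusted p for titration without nitrite and for nitrite with the control plasmid. The nsrR transcription unit lay at -0.21 (adjusted p = 0.411) and 0.00 (adjusted p = 0.988), and the OxyR regulon at 0.16 (adjusted p = 0.26) and 0.00 (adjusted p = 0.988). SoxRS and Mar lay at -0.22 (adjusted p = 0.124) and -0.07 (adjusted p = 0.732), although soxS, the regulator gene of the superoxide response, was lower in both (-0.88 and -0.83). Fry did call SoxRS and Mar lower in titration without nitrite (fry adjusted p = 0.0127). Methionine synthesis had means of 0.00 (adjusted p = 0.835) and 0.00 (adjusted p = 0.971), and arginine synthesis 0.01 (adjusted p = 0.975, with median and test pointing down) and -0.01 (adjusted p = 0.971). RpoS general stress lay at 0.26 (adjusted p = 0.0529) and 0.18 (adjusted p = 0.287), and the lac operon at 0.36 (adjusted p = 0.105) and -0.20 (adjusted p = 0.598). The NorR regulon had probes for norV and norW only and was not tested as a list. The mean of norV, the flavorubredoxin gene, was -0.36 with pGIT1, -0.16 with pGIT1 and nitrite, and 0.35 with pGIT8 and nitrite. That of norW, its reductase, was -0.60, -0.46 and 0.76.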

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

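The tests on the order of the spots, on duplicate spots, on probes low in both comparisons with the reference and on the exchange of a pair of arrays were chosen only after the result was seen, while the test of the nap-ccm operon on pGIT1 replicate 4 and the counts of other splits were planned before theirs.

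The column of pGIT1 replicate 4 matched no other array spot by spot. A failed hybridisation was argued against by its duplicate spots, which correlated with Spearman's rho of 0.891 across genes, within the 0.803 to 0.967 of the other arrays. A nitrite culture under the wrong label was argued against by the nap-ccm operon, whose mean with the blocks in order was 0.216, below the 0.732 to 1.69 of the nitrite arrays. Blocks of spots deposited in another order may account for the pattern, since 47 of 48 blocks matched the mirror block best and 0 matched their own place. With the blocks in order ytfE lay at 4.59, a signal in data that the comparisons did not use, and Spearman's rho across genes was 0.681, 0.289 and 0.873 with pGIT1 replicates 1, 2 and 3, and from -0.529 to 0.623 with the nitrite arrays.

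Probes without a named gene were not part of the comparisons, yet of 6598 tested, 1480 passed in titration without nitrite (215 higher, 1265 lower) and 2710 in nitrite with the control plasmid (283 higher, 2427 lower). Low in both were 904, where independent lists would share 465, and high in both 137, where they would share 9.22. Of the 904, 31 (3.43%) differed between groups, but so did only 1.68% of all 6598, so a low share was given beforehand and decides nothing about a bias of dye or reference, which would cancel between groups. For named genes 18 were low in both, where 5.40 were expected, among them rhaM, paoC, phoE, yafE, ykgF and soxS, and 22 were high in both, where 4.62 were expected. Of the 18, 0 (0%) differed between groups, but a change that both treatments bring in full would look the same, so bias and biology cannot be told apart for these probes and genes.

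Exchanging pGIT1_NO2 replicate 2 and pGIT8_NO2 replicate 3 between their groups gave 1989 genes, against 13 with the groups as labelled. Exchanged labels were argued against by ytfE, which lay at 3.56 on pGIT8_NO2 replicate 3, within the 2.39 to 3.66 of the other arrays of its group, and at 4.69 on pGIT1_NO2 replicate 2, and by hcr (2.42 and 3.07), but not by hmp, which lay higher on the first (3.93) than on the second (3.64). A trend shared by many genes, which may go with spot brightness, was scored under the exchanged labels and removed, and the exchanged split then called 9 genes and the labelled one 6, so the trend remains a candidate explanation for most of the 1989. A first form of this test, with the trend scored under the given labels, left 502 genes as labelled and 0 exchanged, but was circular. The trend took 53.8% of the variance within groups under the exchanged labels and 78.9% under the given ones, where all 54 ribosomal protein genes scored above the median, and no biological explanation was tested.

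Other splits of the arrays into groups of the same sizes were counted. For titration with nitrite chance could not be excluded, since 2 of 35 splits gave as many genes (real 13, highest other 1989), and the highest points to a structure among the arrays rather than to the groups. Its 4 list calls were reached by 31 of 35 splits (highest other 15), so chance could not be excluded there either. For nitrite under titration only the real split of 35 gave as many as 83 genes (highest other 0 by limma). It alone also gave 14 lists, by a margin of 1 list (highest other 13), but their number was 9 to 14 with 1 array left out. The share cannot fall below 1 of 35, and the tests by splits were not adjusted for their number. For the 83 genes the result argues against chance without excluding it, and for the lists the margin is too small to say so. For the 27 genes of the interaction 9 of 100 splits gave as many (highest other 1460). These splits cannot decide on chance. The interaction keeps 1 log ratio against the reference, so a gene with the same ratio on all arrays has a value other than 0 in every split. For the overlap of 36 genes in nitrite only the real split of 100 gave as many (highest other 23). Its part with pGIT8 was tested against 0, so the splits are no clean measure of chance there. The overlap of 2 genes in titration was reached by 2 of 100 splits (highest other 66), but it draws on the 13 genes for which chance could not be excluded, so nothing was built on it. Titration without nitrite and nitrite with the control plasmid were tested against 0 and have no other split.

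The interaction, which keeps 1 log ratio against the reference and is no difference between groups alone, was passed by 27 genes. The named ones were paoC (4.11), rhaM (2.42), cspA (1.91), yafE (1.58), ykgF (1.53), ygbA (-1.95), nrfA (-1.94), yccM (-1.90), nrfE (-1.55) and nrfF (-1.43). For paoC, rhaM, yafE and ykgF, low in both comparisons with the reference, a bias of dye or reference alone would give a positive value, and for ygbA, nrfA, yccM, nrfE and nrfF, high in both, a negative one.

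Single arrays stood apart from the other 3 of their group for 16 of 221 named genes in pGIT1_NO2 and for 3 in pGIT8_NO2, where chance gives about 1 in 20, and the 3 pGIT1 arrays were too few to be tested. On pGIT1_NO2 replicate 4 these were argH (-0.40), cusR (0.084), dcuB (-0.98), fdnH (-0.46), fumB (-0.93), hyaA (-0.47) and ynfG (-0.43). On pGIT1_NO2 replicate 2 they were gadW (-0.11), mqsR (0.49), napC (1.04), nirB (1.38), nirD (-0.56) and nusA (-0.036). On pGIT1_NO2 replicate 3 they were ccmD (0.92) and cysG (0.46), and on replicate 1 yafE (-1.23). On pGIT8_NO2 replicate 4 they were cysU (-0.48) and sodA (0.0575), and on replicate 3 rplN (0.54).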

How the results depend on the processing

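The alternatives with all 12 arrays as deposited, with 12 arrays and blocks in order, and with the shared trend removed were chosen after seeing the data, and the others were planned. All 3192 genes had a value on all arrays, and 3202 of 3204 genes had 2 probes, whose median is their mean. Values on all arrays and the median of a gene's probes could therefore hardly change a count, and are no test of it. Requiring at least 2 values per group could add only genes left out of the 3192. In the numbers of alternatives passed, these settings nearly repeat the main result. Neither they nor a robust prior moved a count by over 1.5 times. Of the 442 results for named genes and 38 called lists none turned past the threshold in the other direction, except nsrR and yjfI under trend removal. Spot intensities were not used, so what signal over background limits is unknown, and the cause of a change was not tested unless one is given.

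Titration without nitrite (159 genes) gave 23 without centring, 388 with quantile normalization, 1884 with every probe on its own, 819 with array weights, 29 at a log2 change of at least 1, 67 with all 12 arrays as deposited, 495 with the blocks in order and 1028 with the trend removed, and 18 to 238 with 1 array left out. Nitrite with the control plasmid (414) gave 31 without centring, 3716 with every probe on its own, 826 with array weights, 74 with only the groups compared, 50 at a log2 change of at least 1, 1168 with the trend removed, and 191 to 1374 with 1 array left out. With only the groups compared, 4 arrays set the spread in place of 11. Titration with nitrite (13) gave 1 without centring, 5 with quantile normalization, 42 with every probe on its own, 1211 with array weights, 0 with only the groups compared (limma, 747 at an unadjusted p under 0.05), 3 at a log2 change of at least 1, 2 with all 12 arrays as deposited, 28 with the blocks in order and 502 with the trend removed, and 0 to 1388 with 1 array left out.

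Nitrite under titration (83) gave 1 without centring, 176 with every probe on its own, 349 with array weights, 29 at a log2 change of at least 1, 151 with the blocks in order and 810 with the trend removed, and 12 to 123 with 1 array left out. The interaction (27) gave 0 without centring, 571 with every probe on its own, 155 with array weights, 15 at a log2 change of at least 1, 0 with all 12 arrays as deposited, 53 with the blocks in order and 475 with the trend removed, and 0 to 88 with 1 array left out. It uses all groups, so a fit of only the groups compared gave no other value. The counts with a larger log2 change required fall by construction, since a condition is added. Those with every probe also take in probes with no named gene. In titration with nitrite 10 named probes and 32 without a named gene passed, and in nitrite under titration 77 and 99. The trend was estimated from the same spread within groups that the test uses, so counts after its removal are not independent of it.

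The overlap in titration (2) gave 1 without centring, 0 with quantile normalization, 306 with array weights, 1 at a log2 change of at least 1, 0 with all 12 arrays as deposited, 12 with the blocks in order and 175 with the trend removed, and 0 to 82 with 1 array left out. The overlap in nitrite (36) gave 1 without centring, 138 with array weights, 9 at a log2 change of at least 1, 69 with the blocks in order and 358 with the trend removed, and 8 to 52 with 1 array left out. Every probe, a robust prior, the median of probes and only the groups compared were not run for overlaps.

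List calls with an estimated correlation were 0 of 9 in titration without nitrite, 0 of 11 in nitrite with the control plasmid, 0 of 4 in titration with nitrite and 1 of 14 in nitrite under titration. For most called lists the estimate lay far above the preset 0.01, as with 0.844 for flagella and chemotaxis, and a larger correlation raises camera's p by its design. It lay below 0 for cold shock (-0.040) and TMAO respiration (-0.085). Why calls of these lists were lost as well was not tested. Fry called 7, 10, 1 and 6 lists, of which 6, 10, 0 and 5 were among those called by camera. Without centring titration with nitrite gave 7 lists, and with the trend removed 5 (3 higher, 2 lower), of which 2 were among the 4. With 1 array left out the calls were 9 to 12, 11 to 11, 4 to 6 and 9 to 14, the 9 of the last without pGIT1 replicate 2.

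The replicate numbers did not pair the arrays throughout. Of 10 pairs with the same number, 5 had correlations of their deviations over 0.1 (from -0.580 to 0.845). Of 11 arrays, 5 correlated best with one of their own number, and the number expected by chance was not worked out. All pairs of replicate 3 correlated positively (0.526, 0.588 and 0.838), while every other number had a pair below 0. A batch shared by arrays of the same number was therefore not excluded. With the number as a block the counts were 99 in titration without nitrite, 430 in nitrite with the control plasmid, 1 in titration with nitrite, 68 in nitrite under titration and 0 in the interaction (limma, 435 at an unadjusted p under 0.05). The overlaps were then 0 and 39, and the list calls 12, 11, 4 and 14.

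Of named genes that passed, 15 of 38 in titration without nitrite, 36 of 46 in nitrite with the control plasmid, 0 of 12 in titration with nitrite, 10 of 26 in nitrite under titration and 0 of 10 in the interaction did so whichever array was left out. With the trend removed, nsrR in nitrite with the control plasmid was 0.15 (adjusted p = 0.0290) against -0.01 (adjusted p = 0.943), and over its alternatives adjusted p ran from 0.0290 to 0.979. In the same comparison yjfI was -0.34 (adjusted p = 0.0181) against 0.05 (adjusted p = 0.878), with a range of 0.0181 to 0.994. The cause was not tested.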

Other observations

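Some genes of shared operons lay outside the rule for named genes and were chosen after their values were seen, and they were not run under the alternatives. All 5 genes of the cytochrome bo oxidase operon were lower in titration without nitrite, where cyoD lay at -1.07 ± 0.17 (SE, n = 3, limma adjusted p = 0.00669) and cyoE at -1.22 ± 0.21 (adjusted p = 0.00952) beside the 3 named in the report. In nitrite with the control plasmid, cyoA lay at -0.32 (adjusted p = 0.341), cyoB at -0.46 (adjusted p = 0.16) and cyoC at 0.09 (adjusted p = 0.75). All 3 lay above 0 on pGIT8_NO2 replicate 3 (0.80, 0.51 and 0.75) and below 0 on the other arrays of that group. In titration with nitrite none of the 5 passed (adjusted p from 0.081 for cyoC to 0.104 for cyoB).

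No list was fixed for formate hydrogenlyase, which splits formate into hydrogen and carbon dioxide, and its genes were not tested as a set. With nitrite and the control plasmid 5 of 9 measured hyc genes passed, all lower. They were hycA, named in the report, hycG (-0.62 ± 0.08, n = 4, limma adjusted p = 0.000941), hycH (-0.71, adjusted p = 0.019), hycF (-0.69, adjusted p = 0.0285) and hycE (-0.69, adjusted p = 0.00222), the last also low in titration without nitrite (-0.59). Not past were hycB (-0.66, adjusted p = 0.233), hycC (-0.16, adjusted p = 0.562), hycD (0.10, adjusted p = 0.898) and hycI (-0.33, adjusted p = 0.0515). The formate dehydrogenase gene fdhF lay at -0.63 (adjusted p = 0.0105). The dimethyl sulphoxide reductase relatives were lower there as well, with ynfE at -1.15, ynfG at -1.02 and ynfH at -0.94. In the broader NsrR set, yoaG was higher with nitrite and the control plasmid (1.46 ± 0.25, n = 4, limma adjusted p = 0.00386), and tehA was higher there (0.43) and in titration without nitrite (0.61).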
